A study of Rattus norvegicus with 8 samples.

How the data were processed

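Gene expression was measured in the epitrochlearis, a small fast-twitch muscle of the rat forelimb, on 8 Affymetrix 3' expression arrays, 1 per rat. Per the labels, 4 rats had received carbohydrate with an amino acid mixture (AAM) after swimming and 4 had received carbohydrate with whey protein hydrolysate (WPH), and each sample was a biological replicate. Biotin-labelled RNA was made from 100 ng of total RNA per the labels' protocols. The groups were read from the treatment labels. The labels name no array batch, and they do not say which 4 rats swam together in a barrel, so neither was entered in a fit. No 2 arrays held the same values.

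The values used were the authors' deposited expression levels on a log2-like scale, 1 per probe set and array, between 5.28 and 14.2. R 2.7.2 is named in the submitters' processing notes, and the background correction, normalization and summary method are not given in the sources used here. Scanner files were not used here, so the scale and centring of the values stay unknown. The median over all probe sets was 6.66 on each array. The deposited differences between arrays were far smaller than usual log2 differences. The SD of a probe set over the 8 arrays had a median of 3.69e-06, the 99th percentile of these SDs was 0.00191, and 23 probe sets ranged over more than 0.1. A deposited difference therefore cannot be read as a fold change. Sizes are given as the standardized difference, which is WPH minus AAM divided by the pooled SD within groups. Its 95% intervals come from the noncentral t distribution on 6 degrees of freedom and cover the error of the SD as well. They do not allow for the choice of genes with small p-values, whose differences tend to be overestimated. The number of arrays limits the precision.

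From the 31099 probe sets, 57 control probe sets were left out and 31042 were tested. Symbols came from the platform annotation, and gene IDs were matched to a current gene table of the GRCr8 assembly. Of the tested probe sets, 20826 had 1 symbol, 436 had several and 9780 were unnamed here. Gene IDs matched for 20758 probe sets, and 0 symbols needed an update. No gene was named from a probe set with several symbols. For gene lists, each of 14217 genes was represented by its probe set of highest mean level.

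WPH was compared with AAM for each probe set by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, prior df 0.549), with Benjamini-Hochberg adjustment and a threshold of 0.05. The unadjusted p-values given for single genes are limma's. Exact two-sided permutation tests over the 35 splits of 8 arrays into 4 and 4 have a smallest possible p of 0.0286. Before the data were examined, 29 pathway lists and 14 cell type marker lists were fixed, each needing 5 measured members. They were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment within each family. Beside it stand camera with an estimated correlation and fry, which tests whether the members of a list move on balance in 1 direction. A list score is the mean over members of the z-score of each gene over the 8 arrays.

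The rule for named genes was also fixed beforehand. It takes the 12 largest changes in each direction past the threshold, filled up with the smallest unadjusted p-values where fewer than 12 passed. It adds up to 4 members of each list past the threshold, up to 2 members of each other list, and 25 genes of exercise, feeding and muscle turnover, all 25 of which were measured.

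The procedure was tested on simulated arrays with the real means and spreads. For WPH against AAM over 31042 probe sets, it recovered 7 of 67 probe sets shifted by 3 SD, 39 of 67 shifted by 6 SD and 66 of 66 shifted by 12 SD, with 2 false calls. Over 14217 independently simulated genes, a list shifted by 0.6 SD was recovered in 100 of 100 simulations, and 0.06 other lists were called per simulation. Genes on real arrays are not independent, and the splits of the real arrays given at the end address that. Rank products over the 16 pairs of arrays, run as an alternative with 100 permutations, made 5171 calls, counted in both directions, over 31042 probe sets on simulated arrays with no change (20 permutations), so their calls are not calibrated here.

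The alternatives fixed beforehand were quantile normalization, median centring, a filter on dim probe sets, the replicate number as a block, leaving out each array, array weights, a trended robust prior, 1 value per gene, rank products, a looser threshold of 0.1 and the other list tests. Added after the data were seen were a fourth-root scale (constant 0.01), unit SD per probe set, camera on ranks, leaving out AAM replicate 3 with WPH replicate 4, and the first principal component as a covariate.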

Results

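The question behind the series is whether whey protein hydrolysate changes muscle gene expression relative to amino acids of the same composition. Whey protein hydrolysate is milk whey protein cut by enzymes into peptides. Male Sprague-Dawley rats, 6 weeks old, swam for 2 h after 3 days of swimming practice. They then received by gavage a meal of 44 kJ, about 15% of a day's energy, holding carbohydrate with either the amino acid mixture (AAM, n = 4) or the hydrolysate (WPH, n = 4). Epitrochlearis muscle was profiled on 1 array per rat. All 8 rats swam and were fed, so no effect of swimming or of feeding itself is measured. The barrel and array batch of each rat are unknown. If they differed between the groups, their effects could not be told apart from that of the meals. The time of sampling after the meal is not given in the sources used here.

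No single gene differed between the meals past the threshold. As a group, genes of cytokines and the inflammatory response were higher after WPH, with 32 of 49 measured members higher. Among them Bcl3, a modulator of NF-kB, was higher by a standardized difference of 3.26 (95% interval 0.948 to 5.49, n = 4 per group). Of its 3 probe sets, 2 were higher after WPH. Il6, a cytokine that muscle releases during exercise, had 2.90 (0.735 to 4.97). Genes of the sarcomere and calcium handling (26 of 33 higher) and immediate early genes (26 of 41 higher) were also higher as groups, the latter with an adjusted p of 0.367 once the correlation was estimated. Lists of amino acid response, protein synthesis and protein breakdown genes did not pass the test. Other divisions of the same arrays gave list calls too, with at least 3 pathway lists in 32 of the 35 possible splits.

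By limma, 0 of 31042 probe sets had an adjusted p below 0.05. The smallest adjusted p was 0.525, for Ttyh1. At an unadjusted p below 0.05 there were 1110 probe sets, 532 higher and 578 lower after WPH, where 1552.1 would be expected by chance. The 4 WPH arrays and the 4 AAM arrays did not overlap for 693 probe sets, or 2.23%, against 2.86% by chance. Rank products made 4776 calls over 4170 distinct probe sets, 606 of which were called in both directions, but on simulated arrays with no change they made 5171 calls.

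The genes with the smallest unadjusted p-values are given as values only, since none passed the threshold. Each gene is represented here by its probe set with the smallest p in that direction. In each of these 24 genes the 4 arrays of one meal did not overlap with those of the other for that probe set. Some genes had other probe sets that went the opposite way. Those going the same way were 3 of 4 for Klf5 and Larp1b, 2 of 3 for Hapln2 and Vps52, and 4 of 5 for Tbl1xr1. Higher after WPH were Ttyh1 (standardized difference 8.49), Atp9a (4.95), Klf5 (4.85), Larp1b (4.32), Zc3h12a (4.23) and Akirin1 (4.27). Zc3h12a encodes a ribonuclease that degrades cytokine transcripts, Il6 among them, and Klf5 encodes a Krüppel-like transcription factor. Bcr, Mtmr6, Ptprs, Acyp2, Tspan13 and Ttc3 completed the higher set, with standardized differences from 3.41 for Ttc3 to 6.35 for Ptprs. Lower after WPH were Ddah1, an enzyme that breaks down inhibitors of nitric oxide synthase (-5.37), Fam98c (-5.13), Unc13b (-5.47), Vps72 (-8.67), Hapln2 (-4.94) and Rhot2 (-3.91). Tbl1xr1, G4, Rnf166, Vps52, Gpr146 and Mylk3 completed the lower set, with values from -3.58 for Vps52 to -4.39 for Mylk3. The deposited differences behind these values were minute. That of Ttyh1 was 7.76e-06 ± 6.47e-07 (SE, n = 4 per group) at a level of 6.28.

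The cytokine and inflammatory response list was the highest-ranked of the 29 pathway lists. Its mean standardized difference was 0.669 and its median 0.333, and camera's adjusted p was 1.28e-05. With an estimated correlation the adjusted p was 0.0286. That estimate, 0.0023, was below the preset 0.01, so a larger correlation does not account for the higher p. Its list score was 0.227 ± 0.248 after WPH and -0.227 ± 0.120 after AAM (SD, n = 4 each), and the 4 WPH arrays all lay above the 4 AAM arrays (exact permutation p = 0.0286, the smallest possible, and 0.414 adjusted over the 29 lists). Beside Bcl3 and Il6, the genes named by the rule were Tnfaip6 (2.73), which encodes a secreted hyaluronan-binding protein, and Socs3 (2.68), a feedback inhibitor of cytokine receptors. Ccl2, which encodes a monocyte chemoattractant, had 1.94, a deposited difference of 0.031 ± 0.011 (SE, n = 4 per group). The deposited difference of Il6 was 1.43e-04 ± 3.49e-05. The mean levels of Bcl3, Il6 and Socs3 were 6.59, 5.85 and 6.48, below the array median of 6.66. No member passed the threshold over all genes or adjusted over the list alone. Macrophage markers had a score of 0.0288 ± 0.688 after WPH and -0.0288 ± 0.744 after AAM, and fibroblast and matrix markers 0.134 ± 1.06 and -0.134 ± 0.484 (SD, n = 4 each). By fry the list's adjusted p was 0.249. The mean standardized difference was 0.396 with quantile normalization and 0.107 with median centring.

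**Figure D1:**
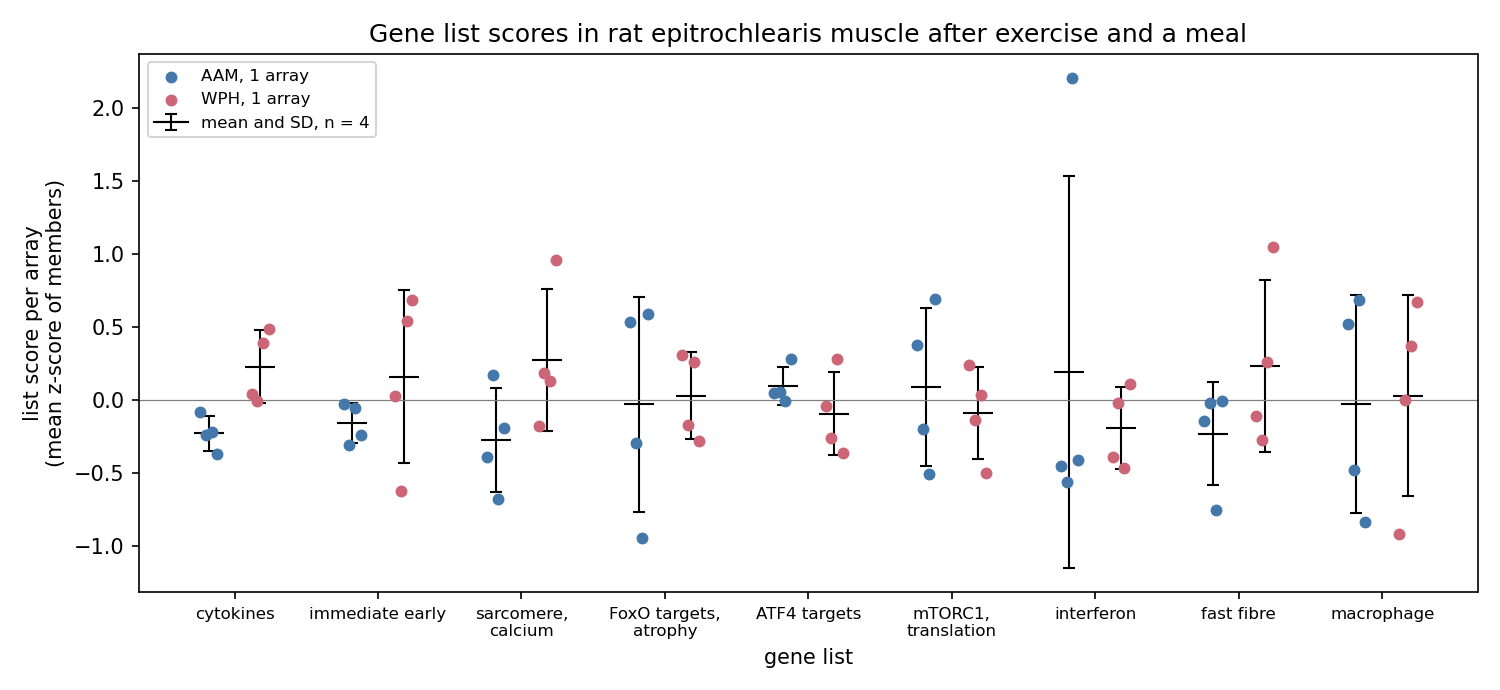
List scores (mean z-score of the members, no unit) of 9 gene lists for each of the 4 AAM and 4 WPH arrays, with the mean and SD of each group. The 4 WPH arrays lie above the 4 AAM arrays for the cytokine list, the groups overlap for the other lists drawn, and AAM replicate 3 stands at 2.20 for the interferon list.

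Sarcomere and calcium handling genes had a mean standardized difference of 0.601 and a median of 0.657, with camera's adjusted p of 7.96e-05. With an estimated correlation, -0.012 and so also below the preset 0.01, the adjusted p was 0.0286. The members named by the rule were Ampd1, the AMP deaminase of muscle (1.91), Pvalb, the calcium buffer of fast fibres (1.41), Mybpc2, the myosin-binding protein C of fast fibres (1.38), and Myoz3, a Z-disc protein (1.24). No member passed over all genes or adjusted over the list alone. The highest list score, 0.958, was that of WPH replicate 4. That array also had the highest score of the fast fibre markers, 1.05. Most fast fibre markers, Pvalb and Mybpc2 among them, are members of the sarcomere list too, so these scores are not independent. The call was lost with quantile normalization (adjusted p = 0.868) and without AAM replicate 3 and WPH replicate 4 (adjusted p = 0.0739). By fry the adjusted p was 0.777. With median centring camera kept the call (adjusted p = 3.69e-04), although the mean standardized difference was -0.118.

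Immediate early genes, which are transcribed within minutes of a stimulus such as contraction, had a mean standardized difference of 0.415 and a median of 0.377, with camera's adjusted p of 0.00429. This call was lost with an estimated correlation (adjusted p = 0.367). The transcription factor genes Junb, Atf3, Nr4a1 and Nr4a3 had standardized differences of 2.25, 2.05, 1.92 and 1.87. Fos had 1.54 and Egr1 1.40. The deposited difference was 0.040 ± 0.014 for Atf3, 0.024 ± 0.0091 for Nr4a3 and 0.048 ± 0.024 for Egr1, and 5.31e-04 ± 1.67e-04 for Junb (SE, n = 4 per group). All 3 probe sets of Nr4a3 were higher after WPH, but only 1 of the 2 of Fos. No member passed over all genes or adjusted over the list alone. The call was also lost without WPH replicate 3 (adjusted p = 0.0901), without WPH replicate 4 (0.268), without AAM replicate 3 and WPH replicate 4 (0.165) and by fry (0.963). Without WPH replicate 2 the mean standardized difference was 1.01 (adjusted p = 6.55e-08).

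**Figure D2:**
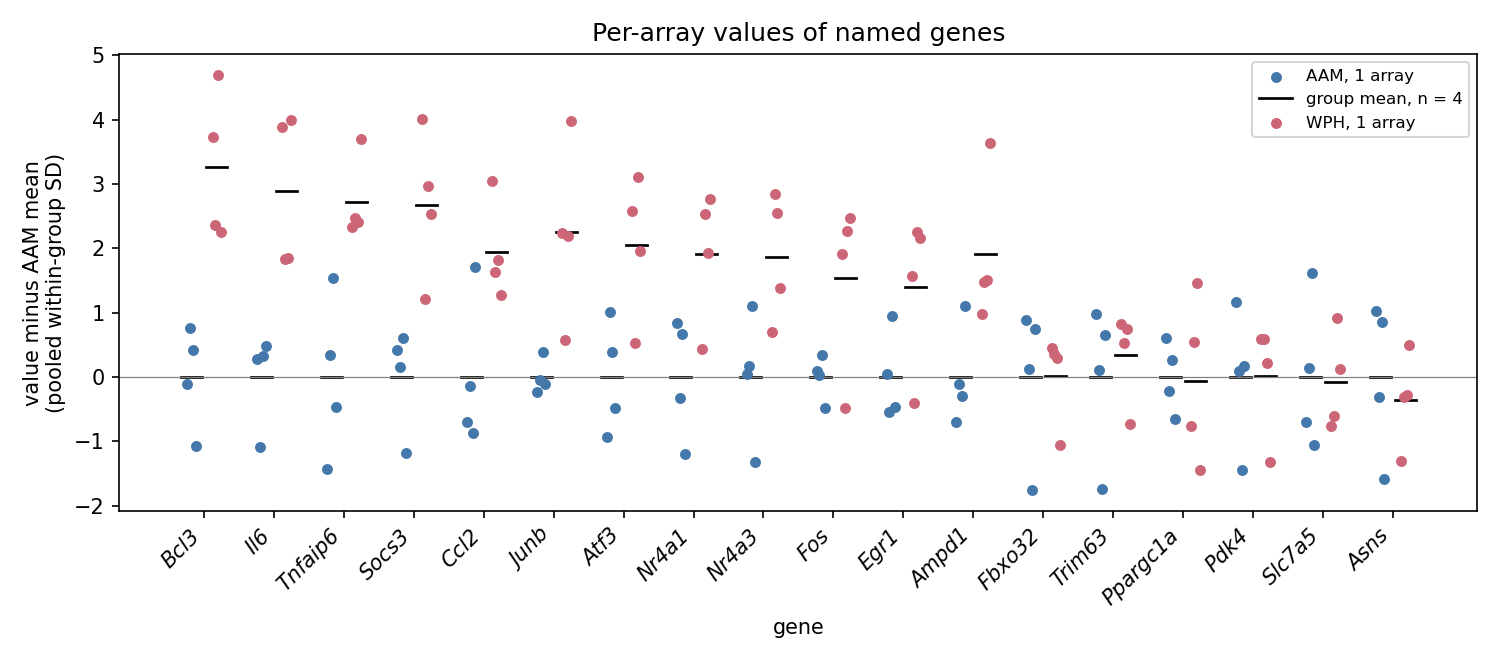
Values of 18 named genes on each of the 4 AAM and 4 WPH arrays, as the distance from the AAM mean in units of the pooled SD within groups, with group means as lines. The WPH means of Bcl3 and Il6 lie at 3.26 and 2.90, while those of Fbxo32 and Pdk4 lie at 0.01 and 0.02.

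Genes that respond to amino acid supply did not pass the test as groups. Of 36 measured ATF4 targets, which are induced when amino acids are scarce, 13 were higher and 23 lower after WPH (camera's adjusted p = 0.634). Asns, the asparagine synthetase gene, had a standardized difference of -0.35. Atf3 and Gdf15, with 2.05 and 1.72, were the members with the smallest unadjusted p-values. Amino acid and peptide transporters were divided evenly, 15 higher and 16 lower (adjusted p = 0.975). Among them Slc7a5 and Slc38a2, transporters of neutral amino acids, had -0.08 and 0.12, Slc16a10 -1.91 and Slc38a4 1.43. Branched-chain amino acid catabolism had an adjusted p of 0.826. Its first step is catalysed by the product of Bcat2, which had 2.98 with groups that did not overlap (exact permutation p = 0.0286), and Acad8 had 1.93. For mTORC1 signalling and translation initiation the adjusted p was 0.507, with Mtor at -0.38, Eif4e at -1.52 and Eif4b at 0.96. For ribosome biogenesis it was 0.852, with Noc3l at 1.70 and Nop2 at -0.82, and without AAM replicate 3 its mean moved from -0.075 to -0.724 (adjusted p = 2.03e-04).

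Protein breakdown and stress genes did not pass either. For FoxO targets and muscle atrophy genes camera's adjusted p was 0.531. The ubiquitin ligase genes of atrophy, Fbxo32 and Trim63, had standardized differences of 0.01 (95% interval -1.38 to 1.40) and 0.34, and the growth inhibitor gene Mstn had 0.33. Mt1, a metallothionein gene of this list and of the oxidative stress and glucocorticoid lists, had 3.00, and Cdkn1a -1.03. Autophagy and lysosome genes (adjusted p = 0.362) included Atg7 at -2.98 and Atg14 at 1.92. Their mean of 0.113 became 0.457 without AAM replicate 4 (adjusted p = 0.0279) and -0.128 without AAM replicate 2 (0.964). Proteasome subunits (0.362) had a mean of -0.225 and included Psmb5 at -1.21 and Psma7 at -0.73. The call of this list changed when 1 array was left out. It was called lower after WPH without AAM replicate 2 (-0.481, adjusted p = 0.0212), AAM replicate 3 (-0.641, 0.00108) or WPH replicate 1 (-0.536, 0.00599). Heat shock proteins and chaperones had an adjusted p of 0.0816, with Dnajb1 at 3.07, Hspe1 at -2.07 and Hspa1a at 1.18. The oxidative stress and metallothionein list had 0.507, with Hmox1 at 1.57. Endoplasmic reticulum stress had 0.781, with Ddit3 at 1.498 and Sel1l at 0.83. Glucocorticoid-induced genes had 0.997, with Mt1 at 3.00, Pik3r1 at -1.11 and Ddit4 at -0.78.

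Energy metabolism showed no list past the threshold. Glucose uptake, insulin signalling and glycogen genes came closest, 22 of 41 higher after WPH with camera's adjusted p of 0.0724. The 4 WPH scores all lay above the 4 AAM scores (exact permutation p = 0.0286, the smallest possible, and 0.414 adjusted over the 29 lists). The list was called without WPH replicate 1 (adjusted p = 0.0224), with the replicate number as a block (0.0418) and on the fourth-root scale (0.0436). With median centring camera called it (0.00315) although its mean turned from 0.299 to -0.186, and with quantile normalization its mean was 0.084 while camera ranked it lower after WPH (0.963). The member with the smallest unadjusted p was Socs3 (2.68), which is in the cytokine list too. Pygm, the glycogen phosphorylase of muscle, had 1.82, and Gys1, its glycogen synthase, -0.48. The glucose transporter gene Slc2a4 had -0.40 and the hexokinase gene Hk2 -0.42. Fatty acid uptake and oxidation genes had an adjusted p of 0.0784, with 26 of 38 lower after WPH and a mean of -0.389. Without AAM replicate 1 the mean was -0.763 (adjusted p = 1.18e-04), and without AAM replicate 3 it was -0.102 (0.934). The list was also called in the brighter part of the probe sets (adjusted p = 0.0432) and on the fourth-root scale (0.0423). Mlycd, the malonyl-CoA decarboxylase gene, had -3.11, Plin5 -1.56, Pdk4 0.02, Ucp3 0.95 and Angptl4 -0.31. Oxidative phosphorylation had 0.826, with Cox5a at 2.50 and Ndufa9 at -1.19. Its mean of -0.110 moved to -0.666 without AAM replicate 1 (adjusted p = 5.03e-05) and to 0.552 without AAM replicate 3 (1.89e-04). The tricarboxylic acid cycle had 0.233, with Mdh1 at -1.27 and Dlst at -1.15, and its mean moved from -0.315 to -0.795 without AAM replicate 1 (adjusted p = 6.36e-04) and to 0.136 without AAM replicate 3 (0.462). Glycolysis had 0.277, with the lactate transporter gene Slc16a1 at -2.19 and Gpi at 1.58. Mitochondrial biogenesis regulators had 0.852, with Esrra at -2.04, Opa1 at 1.12 and Ppargc1a at -0.05. Sterol synthesis and uptake had 0.852, with Cyp51 at 2.15 and Hsd17b7 at -0.81. Fatty acid and triglyceride synthesis had 0.852, with Dgat1 at -1.45 and Fasn at 1.07.

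The remaining pathway lists concern signalling, growth and immunity. NF-kB, MAPK and phosphatase feedback regulators had camera's adjusted p of 0.0724, with 18 of 26 higher after WPH, Socs3 at 2.68 and Dusp2 at 1.28. Its mean of 0.372 became 0.702 without WPH replicate 2 (adjusted p = 6.15e-04) and 0.119 without WPH replicate 4 (0.712), and the list was also called without AAM replicate 1, AAM replicate 3 or WPH replicate 1 (0.0143, 0.0421 and 0.0195). Interferon response genes had 0.0784, with 27 of 29 lower after WPH, Ifit1 at -1.78 and Irf1 at 1.95. AAM replicate 3 set that direction, and without it the list was higher after WPH (adjusted p = 1.56e-06). Myogenesis and growth had 0.0949, with Mef2c at 2.40, Igf1r at 1.49 and Igf1 at -0.21. The circadian clock had 0.0949, with Npas2 at 1.44 and Csnk1d at 1.29. Cell cycle genes had 0.152, with Mcm2 at -2.86 and Bub1 at -0.95. Angiogenesis and hypoxia had 0.852, with Vegfa at 0.20, Car9 at -1.99 and Nos1 at -1.51.

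None of the 14 marker lists of cell types passed. The lowest adjusted p by camera was 0.168, both for skin and epithelium markers, 13 of 16 lower after WPH, with Epcam at -1.66 and Ivl at -1.59, and for fast fibre markers, 9 of 11 higher. The 4 WPH scores of the skin and epithelium list all lay below the 4 AAM scores. Its exact permutation p was 0.0286, the smallest possible, and 0.4 adjusted over the 14 marker lists. By camera, fibroblast and matrix markers followed with an adjusted p of 0.185, with Col6a1 at 0.83 and Fmod at 0.81. Then came endothelium with 0.232, with Tie1 at 1.17 and Flt1 at 1.13. The calls of both changed when 1 array was left out. The fibroblast and matrix mean of 0.261 became 0.674 without WPH replicate 2 (adjusted p = 5.62e-04) and -0.226 without WPH replicate 4 (0.562), with calls also without AAM replicate 3 (0.0342) or WPH replicate 1 (0.0277). The endothelium mean of 0.333 became 0.974 without AAM replicate 3 (0.00551) and 0.046 without AAM replicate 2 (0.927). Lymphocyte markers had 0.527, with Cd4 at -1.45 and Cd79b at -1.11. Smooth muscle and pericyte (Acta2 at 1.76), Schwann cell and nerve (Mag at -1.87) and satellite cell markers (Ncam1 at 1.93) each had 0.703. Mast cell (Fcer1a at -2.42, Hdc at 1.83), macrophage (Adgre1 at 0.85, Lyz2 at 0.45) and neutrophil markers (Cxcr2 at -1.33, Mmp8 at 1.12) each had 0.723. Erythrocyte (Slc25a37 at -1.11), adipocyte (Car3 at 0.80, Aqp7 at -0.78) and slow fibre markers (Csrp3 at 1.15, Myh7 at -0.68) each had 0.733.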

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

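The tests of single lists across the splits, both tests on leukocyte markers and the fits with the first principal component were chosen after the results were seen. Within a group of 4 arrays, 1 array stood far from the other 3 by Dixon's ratio in 17 of 346 tested groups of named genes and list scores, where 17.3 are expected by chance. Among the AAM arrays the ratio was 0.89 for Acyp2, 0.971 for G4 and 0.901 for Adgre1 (replicate 4 low in each), and 0.869 for Il6 (replicate 2 low). AAM replicate 3 was high for Mlycd (0.908), Irf1 (0.868) and Ucp3 (0.963) and low for Cd79b (0.85). The interferon list score was high in AAM replicate 3 (0.946), and the skin and epithelium score was high in AAM replicate 2 (0.832). WPH replicate 4 was low for Tbl1xr1 (0.841), Slc2a4 (0.841) and Fbxo32 (0.902) and high for Tnfaip6 (0.903). WPH replicate 1 was low for Vegfa (0.883). WPH replicate 3 had high scores of the amino acid and peptide transporters (0.873) and of endothelium (0.851).

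The interferon pattern was broad within its array. AAM replicate 3 had a list score of 2.20, and the other 7 arrays lay between -0.563 and 0.109. Against 10000 random lists of the same size and level, this score lay at percentile 100, and the highest random list had 0.807. The score thus lay above the general level of that array. Random lists hold genes that need not vary together, whereas the estimated correlation of the interferon list was 0.763. Among others, oxidative phosphorylation (1.66), the tricarboxylic acid cycle (1.48) and erythrocyte markers (1.31) also exceeded 0.807 there. A change of that array that reached many lists is therefore not excluded. Leukocytes in that muscle piece stay open, since its pooled leukocyte marker score, 0.327, was the highest of the 8 arrays but close to the next, 0.207. A candidate explanation is an interferon response in that 1 rat, and no group of the design tests it.

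The cytokine list is the call that held best. The difference of its mean score was 0.454 for the meals and at most 0.418 for the other splits. The list was picked among 29, and at least 1 pathway list had its largest difference at 14 of the 35 splits. To exclude chance, all 29 lists would have had to peak at the same split, so this count decides nothing. Chance is not excluded. The meals were the peak of 2 lists, and the highest other split was the peak of 6. The first principal component as a covariate left camera's adjusted p at 3.49e-05. That component ran from -107.1 to 152.5 over the AAM arrays and from -70.5 to 103.3 over the WPH arrays. It hardly divided the meals, so as a covariate it could hardly remove a difference between them, and the fit decides nothing. More leukocytes in the WPH pieces are not excluded, since the cytokine score minus the leukocyte marker score gave an exact permutation p of 0.0571. The leukocyte score itself (43 markers) was not higher after WPH. It differed by -0.0871, against 0.462 for the cytokine score without the 1 shared gene. Leukocyte scores ran from -0.539 to 0.207 over the WPH arrays and from -0.529 to 0.327 over the AAM arrays.

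For the sarcomere list, 4 of the 35 splits gave a difference as large (0.545, the highest other 0.720), so chance is not excluded. The first principal component as a covariate left camera's adjusted p at 3.09e-04, which decides nothing, since that component hardly divided the meals. Without WPH replicate 4 the adjusted p was 0.0223, and the mean standardized difference was 0.417 against 0.601 with all arrays. Without AAM replicate 3 as well, the call was lost (0.0739). Camera called lists in most splits, so a kept call does not exclude WPH replicate 4 as the cause. For the immediate early list, 11 of the 35 splits gave a difference as large (0.318, the highest other 0.614).

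Chance is not excluded for the count of pathway lists, of unadjusted p-values or of rank product calls. As many pathway lists as the 3 of the meals, or more, were called in 32 of the 35 splits, with 15 in the highest other split and a median of 7.5 over the other 34. Camera at its preset correlation thus called lists in most divisions of these arrays. For the 0 marker lists and the 0 probe sets past the adjusted threshold the comparison decides nothing, since all 35 splits reach a count of 0. The highest other counts were 6 and 1. For unadjusted p-values, 24 of the 35 splits gave at least the 1110 probe sets of the meals. The highest count, 4002, came from AAM replicates 1 and 4 with WPH replicates 1 and 2 against the rest. It was picked as the highest of the other 34 splits, and how high such a count would be by chance was not tested. Rank products, with 20 permutations, gave at least the 4768 calls of the meals in 22 of the 35 splits, the highest other count being 6663.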

How the results depend on the processing

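The first principal component covariate, the fourth-root scale and leaving out both AAM replicate 3 and WPH replicate 4 were chosen after the data were seen, as were unit SD per probe set and camera on ranks. Against 0 probe sets by limma, quantile normalization gave 5 (4 higher and 1 lower after WPH), the principal component covariate 1 (Rnf166), rank products 4776 calls (4170 distinct probe sets) and each other setting 0, as did leaving out any array (0 to 0). The 1110 probe sets at an unadjusted p below 0.05 (532 higher, 578 lower) became 486 with quantile normalization (182 higher, 304 lower), 172 with median centring and 1015 to 1377 without 1 array. They became 447 in the brighter part of the probe sets, 450 with 1 probe set per gene and 460 with gene means, where fewer were tested (15521, 14217 and 14217). Quantile normalization and centring move values by more than most probe sets vary. The largest shift of an array median, 4.56e-05, exceeds the SD of 87.5% of the probe sets.

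The 3 pathway lists became 11 with median centring, 8 on the fourth-root scale, 5 with the principal component covariate and 0 by fry. Leaving out 1 array gave 2 to 8 lists, with 8 without AAM replicate 1, 3 or 4, 7 without WPH replicate 1 and 5 without AAM replicate 2 or WPH replicate 2. The lists added by leaving out 1 array were the feedback regulators (AAM replicates 1 and 3, WPH replicates 1 and 2), interferon (AAM replicates 1 to 4, WPH replicate 4), oxidative phosphorylation (AAM replicates 1 and 3), tricarboxylic acid cycle and fatty acid oxidation (AAM replicate 1), proteasome (AAM replicates 2 and 3, WPH replicate 1), ribosome biogenesis (AAM replicate 3), autophagy and cell cycle (AAM replicate 4), circadian clock (AAM replicate 4, WPH replicate 2), heat shock (AAM replicate 4, WPH replicate 4), and glucose uptake and myogenesis (WPH replicate 1). The 0 marker lists became 2 with median centring, 1 without AAM replicate 3 and WPH replicate 4, and 0 to 2 without 1 array. The cytokine list stayed past the threshold in every camera setting, with adjusted p up to 0.0286, but its mean standardized difference fell from 0.669 to 0.396 with quantile normalization and 0.107 with median centring. The interferon list turned to a mean standardized difference of 0.927 without AAM replicate 3 and 0.693 without that array and WPH replicate 4. Oxidative phosphorylation turned to 0.552 and 0.470. Without 1 array they ranged from -0.614 to 0.927 and from -0.666 to 0.552. AAM replicate 3 had the highest score of both lists. For the other changes the cause was not tested.

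With the replicate block, 0 probe sets passed, 1367 had an unadjusted p below 0.05 and 4 pathway and 0 marker lists were called. Same-numbered arrays correlated at 0.157, 0.134, 0.0640 and -0.0708 in their deviations from the group means. WPH replicates 1, 2 and 3 each correlated best with the AAM array of the same number. The highest correlation of any pair was 0.279, between AAM replicate 3 and WPH replicate 4. Whether same-numbered arrays belong together thus stays open. Among 130 named genes, 48 changed sign with quantile normalization, 23 with median centring and at most 7 without 1 array. A pseudocount was not run, since the values are on a log scale. Signal over background was not analysed here.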

Other observations

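The genes, lists and relations in this part were chosen after their values were seen. Fam111a had a deposited difference between the meals of 0.23 ± 0.14 (SE, n = 4 per group), with a standardized difference of 1.18 and an exact permutation p of 0.171. The interferon-induced genes Mx1, Irf7 and Isg15 differed by -0.056 ± 0.060, -0.038 ± 0.058 and -0.034 ± 0.068 (SE, n = 4 per group), within the spread between arrays. Ankrd1, a gene of the stretch response in muscle, differed by 0.053 ± 0.061, also within the spread.

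Slow fibre markers divided the WPH arrays, with scores of 0.850 and 0.802 in replicates 1 and 2 against -1.06 and -0.861 in replicates 3 and 4. Oxidative phosphorylation ran from -1.35 in AAM replicate 1 to 1.66 in AAM replicate 3. Over the 8 arrays its score ran opposite to that of proteasome subunits, with Pearson's r = -0.784 (exact permutation p = 5.95e-04) and Spearman's rho = -0.881 (exact permutation p = 0.00724). It also ran opposite to ribosome biogenesis, with r = -0.872 (exact permutation p = 0.00124) and rho = -0.905 (exact permutation p = 0.00456). Proteasome subunits and ribosome biogenesis ran together, with r = 0.934 (exact permutation p = 9.92e-05) and rho = 0.976 (exact permutation p = 3.97e-04). Without the 2 arrays farthest from the median of the oxidative phosphorylation score, r was -0.937 and -0.798. For the last pair it was 0.886 without the 2 farthest by the proteasome score and 0.940 without the 2 farthest by the ribosome biogenesis score. The 3 relations were picked among 903 pairs of list scores. Adjusted over all 903, the exact permutation p-values for r were 0.0896, 0.134 and 0.0448, so the first and second did not pass. The other pairs with an adjusted exact permutation p of 0.0448 were FoxO targets with autophagy (r = 0.953) and with mTORC1 signalling (r = 0.909), which share 3 genes in each case, and branched-chain amino acid catabolism with mitochondrial biogenesis regulators (r = 0.964). Their unadjusted exact permutation p-values for r were 4.96e-05, 1.49e-04 and 1.98e-04. Spearman's rho was 1, 0.976 and 0.952 (exact permutation p = 4.96e-05, the smallest possible, 3.97e-04 and 0.00114), and r was 0.910, 0.923 and 0.974 without the 2 arrays farthest from the median of the FoxO, mTORC1 and branched-chain amino acid scores. For the 3 picked relations, scores were also centred on the group means and permuted within groups. Oxidative phosphorylation then had r = -0.805 with proteasome subunits (exact permutation p = 0.00694) and -0.881 with ribosome biogenesis (exact permutation p = 0.0104). Proteasome subunits with ribosome biogenesis had 0.937 (exact permutation p = 0.00347, the smallest possible). These p-values were not adjusted for the choice. The first principal component held 25.5% of the variance, with AAM replicates 1 and 3 at its ends, and whether these lists follow it more than other genes do was not tested.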
